A study of Candida albicans with 9 samples.

How the data were processed

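RNA was sequenced from Candida albicans SC5314 after 6 h at 30 °C, in 3 control libraries, 3 libraries with 0.5 µg/mL Amb and 3 libraries with 0.5 µg/mL Amb and 8 µg/mL rimonabant. RNA was taken with a yeast RNA kit and libraries followed a standard Illumina protocol, per the labels. The deposited table holds FPKM (fragments per kilobase of gene model, relative to the mapped fragments of the library) to 2 decimals for 6090 identifiers in the 9 libraries, with no further scaling between libraries stated by the authors. The submitters' processing notes name HISAT2, Cufflinks 2.2.1 and DESeq2 with no role or order. They give no genome build, annotation version or strandedness, so no coordinates are given. Read totals were not available here, so the depth of the libraries is unknown. Library columns were matched to the groups by their names, and every column was matched.

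Of the 6090 identifiers, 6030 matched a locus tag of the reference gene table and 2821 of these had a symbol, while 60 were not in the table and are called unmatched. The reference table was used only for symbols, length and gene order. Lengths are called coding lengths below, since 95.7% were multiples of 3. The rest, such as those of SOD1 (710 nt), RPS21B (641 nt) and ATP1 (2143 nt), cannot be coding sequence alone. Length classes and sums of FPKM times coding length are therefore approximate. The 60 unmatched identifiers had no coding length and are left out of both. In 10 sets, 20 identifiers carried the same values in every library, TSA1 with TSA1B and HSP12 with a gene without a symbol among them, and reads may be shared within such sets.

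Values were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 9 libraries were tested (5962, with 128 below). A linear model with a mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with moderated variances and a mean-variance trend, 2-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 3 comparisons were Amb with control, the combination with control, and the combination with Amb. Count-based tests were not used, since the table holds no counts. For genes with a value of 0 in a group the values are given per library and no fold change is printed, because such a fold depends on the pseudocount. Fold changes of genes with a group mean near or below 1 FPKM, such as AGA1 in control (0.440 FPKM), are printed but depend on it too.

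Gene lists for 27 processes of this yeast were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. One list, of mitochondrially encoded genes, had no member in the table and is not analysed here. The other 26 were tested with limma's camera at a preset correlation of 0.01 between genes and, beside it, with an estimated correlation, adjusted over the lists of a comparison. Ribosomal proteins were taken by symbol, a rule that also takes in RPP1, whose symbol is that of an RNase P subunit in budding yeast. Named genes were, in each comparison, the 8 with the largest increase and the 8 with the largest decrease among genes with a symbol that passed the test, had at least 10 FPKM in the higher group and no overlap between groups, then up to 3 members with the largest changes of each list described, and ERG11, ERG3, ERG6, ERG1, CAT1, SOD1, SOD5, CDR1, ECE1 and FTR1 in any case. Genes of the same rule without a value of 0 were added after the values were seen, and so were HSP104 with the combination, CDR2, SNQ2 and TAC1 where they are named outside the rule, and MDR1 and TPO3 with the combination against Amb.

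The overlap of both comparisons with control was set against independent calls and against 100 draws of simulated unchanged groups with the same 3 controls. The test was tried on simulated data with 200 changed genes of 5962. It recovered 68%, 69% and 71% of genes changed by 1 on the log2 scale and 91%, 91% and 97% of those changed by 2 in the 3 comparisons, with 14, 14 and 6 false calls among 173, 174 and 174 calls. In the real data 58.8% to 86.8% of genes passed the test, and the simulation held no common shift of all genes. These rates therefore need not hold for the real data. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean of at least 5 FPKM), scaling (to a common sum, median of ratios, quantile), the variance model, the libraries in the fit, a minimum change of 1 on the log2 scale, a replicate block, and leaving out each library in turn. A further 3, added after the data were seen, left out genes under 300 nt, left out genes with any 0, and removed a trend with coding length. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.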

Results

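The transcriptome of Candida albicans SC5314, a widely used laboratory strain of this fungal pathogen, was measured by RNA sequencing in 9 libraries that fell into 3 groups of 3. The cells had been kept for 6 h at 30 °C in RPMI1640, a defined culture medium. The control group received the solvent dimethyl sulfoxide. The second group received 0.5 µg/mL of the compound labelled Amb, taken here as amphotericin B, a polyene antifungal that binds the membrane sterol ergosterol. The third group received 0.5 µg/mL Amb together with 8 µg/mL rimonabant, an antagonist of a cannabinoid receptor of mammals, and is called the combination below. No libraries of rimonabant alone were described, so the comparison of the combination with Amb shows what rimonabant added in the presence of Amb. Expression was given as FPKM for 6090 genes in every library. The number of reads behind each library was not given, so the depth is unknown and no counting interval can be stated.

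The libraries of a group were much alike and the groups were far apart. On the log2(FPKM + 1) scale, the correlation across genes was 0.966 to 0.988 between libraries of one group. It was 0.654 to 0.670 between control and Amb, 0.540 to 0.554 between control and the combination, and 0.863 to 0.880 between Amb and the combination. Genes are not independent replicates, so these values describe similarity only. FPKM values summed to 1489519 to 1542321 per library in control, 1380825 to 1392100 under Amb and 1116501 to 1135472 with the combination. The median gene stood at 25.4 ± 0.389 FPKM in control, 14.8 ± 0.490 under Amb and 10.8 ± 0.998 with the combination (SD, n = 3). From 98 to 110 genes were listed at 0 in the control libraries, 143 to 160 in the Amb libraries and 198 to 272 in those of the combination. Genes of cytosolic ribosomal proteins held 15.9% ± 0.512 of the summed FPKM in control, 0.737% ± 0.0603 under Amb and 0.212% ± 0.0271 with the combination (SD, n = 3).

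**Figure D1:**
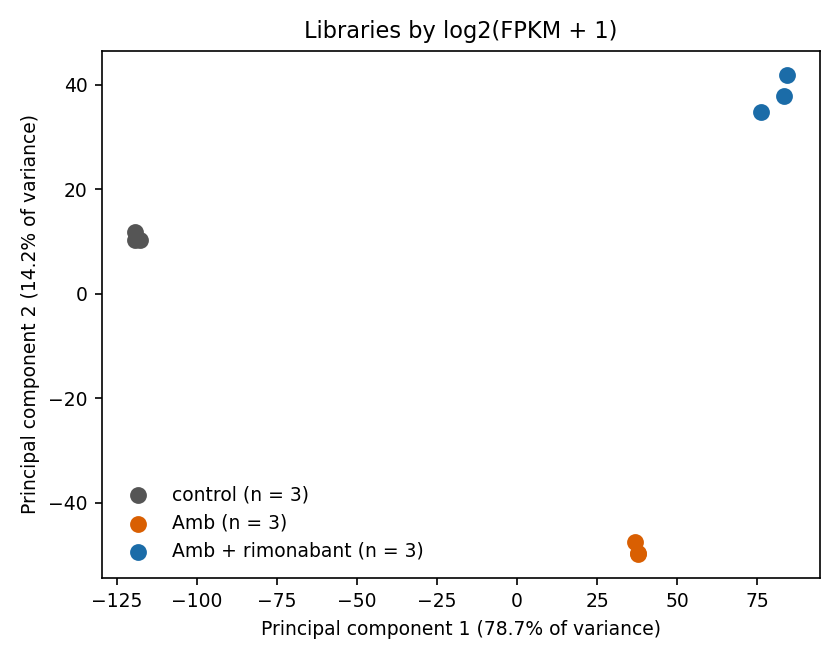
Each point is 1 of the 9 libraries, placed by its scores (log2 units) on principal component 1 (x axis, 78.7% of the variance) and principal component 2 (y axis, 14.2%) of log2(FPKM + 1), and coloured by group. The 3 libraries of each group lie close together and apart from those of the other groups.

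In all comparisons, gene values are mean FPKM ± SD over the 3 libraries of a group, and changes are log2 fold changes ± SE from limma with an adjusted p. For every gene named below as having risen or fallen, the 3 libraries of one group all lay on one side of the 3 of the other, except where stated, while counts of genes that rose or fell follow the limma call alone. The median log2 fold change of all 5962 genes tested was −0.77 for Amb against control, −1.11 for the combination against control and −0.23 for the combination against Amb, and list medians are to be read against these values. After median-of-ratios scaling these medians were −0.06, −0.14 and 0.01. That scaling aligns the middle of the libraries, so smaller medians and more even splits of higher and lower genes follow largely from it. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All 33 gene list calls given below were made with a preset correlation between genes, and none held with an estimated one (the smallest adjusted p with an estimated correlation was 0.192, 0.258 and 0.363 in the 3 comparisons).

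The comparison of Amb with control asked how the polyene alone changed expression. Under Amb, genes that build ribosomes and genes that ferment glucose fell steeply, while most members of the list of glyoxylate cycle, fatty acid oxidation and gluconeogenesis genes and of the heat shock and chaperone list rose. PDC11, the pyruvate decarboxylase of ethanol fermentation, stood at 4408 ± 56.2 FPKM in control and 58.0 ± 8.45 under Amb, a change of −6.23 ± 0.09 (adjusted p = 8.36e-11). HSP104, a disaggregase of heat-damaged proteins, rose from 254 ± 7.82 to 5508 ± 131 FPKM, a change of 4.43 ± 0.05 (adjusted p = 3.16e-11). CDR1 (CAALFM_C305220WA), the main ABC transporter of azole efflux, fell from 2585 ± 39.4 to 269 ± 19.7 FPKM (−3.26 ± 0.06, adjusted p = 1.95e-10). Of 5962 genes, 1570 rose and 3329 fell, and 1063 did not pass the test.

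Transcripts of ribosome and proteasome genes were lower under Amb. Of 73 cytosolic ribosomal protein genes, 70 fell and 2 rose, with a median of −5.54 (adjusted p = 3.01e-09; adjusted p = 0.210 with an estimated correlation). RPL9B fell from 2259 ± 83.8 to 14.2 ± 2.05 FPKM (−7.22 ± 0.33) and RPL21A fell from 1804 ± 73.5 to 15.5 ± 4.69 FPKM (−6.82 ± 0.29). RPP2A, listed at 0, 6.36 and 0 FPKM in the Amb libraries, had averaged 1698 ± 165 FPKM in control. Among 63 ribosome biogenesis genes 53 fell and 4 rose, with a median of −1.71 (adjusted p = 0.00255; adjusted p = 0.513 with an estimated correlation). PWP1, UTP4 and ERB1, which act in the assembly of the ribosomal subunits, changed by −3.83, −3.82 and −3.81. Their means under Amb, 0.713, 1.27 and 1.09 FPKM, lay near the pseudocount of 1, so the size of these changes depends on it. All but 2 of the 27 proteasome genes fell and none rose, with a median of −1.69 (adjusted p = 0.00158; adjusted p = 0.192 with an estimated correlation), and after median-of-ratios scaling 16 fell and 4 rose with a median of −0.92. Among them were PRE2 (−4.79 ± 0.16), RPN1 (−3.63 ± 0.17) and PRE6 (−3.08 ± 0.15).

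Genes of carbon metabolism changed in several lists. All 18 genes of glycolysis and ethanol fermentation fell, with a median of −3.58 (adjusted p = 6.98e-06; adjusted p = 0.193 with an estimated correlation). Besides PDC11, the enolase gene ENO1 fell from 5302 ± 123 to 199.6 ± 12.7 FPKM (−4.73 ± 0.06) and PGI1, which encodes glucose-phosphate isomerase, changed by −5.37 ± 0.22. Of 35 nuclear genes of the respiratory chain and ATP synthase, 28 fell and 5 rose, with a median of −1.78 (adjusted p = 0.0440; adjusted p = 0.513 with an estimated correlation). The ATP synthase genes ATP1 and ATP2 changed by −4.93 ± 0.15 and −4.24 ± 0.08, and CYT1, for cytochrome c1, by −4.61 ± 0.14. The respiratory call ended without Amb library 1 (adjusted p = 0.0507), with a pseudocount of 5 (adjusted p = 0.0550), with a mean of at least 5 FPKM (adjusted p = 0.0519), without a mean-variance trend (adjusted p = 0.0512), without genes under 300 nt (adjusted p = 0.0670) and without genes with any 0 (adjusted p = 0.0547). In the opposite direction, 25 of 29 genes of the glyoxylate cycle, fatty acid oxidation and gluconeogenesis rose and 3 fell, with a median of 1.19 (adjusted p = 2.94e-08; adjusted p = 0.365 with an estimated correlation). POX1, a predicted acyl-CoA oxidase, rose from 27.3 ± 1.52 to 329.7 ± 20.6 FPKM (3.54 ± 0.07), and the thiolase gene POT1 rose from 47.4 ± 4.67 to 395 ± 9.35 FPKM (3.04 ± 0.08). Both belong to fatty acid oxidation, and the list pools several pathways. Of the glyoxylate cycle genes, ICL1 held 0.303% of summed FPKM times coding length in control and 0.161% under Amb. MLS1 held 0.157% and 0.172%, so the list call does not show a rise of the glyoxylate cycle itself. The list of hexose transporters went both ways, with 10 of 19 members higher and 9 lower (adjusted p = 0.25). HGT17 rose from 38.2 ± 2.80 to 2482 ± 166 FPKM (5.98 ± 0.08), whereas HGT8 fell from 16277 ± 93.7 to 541 ± 23.4 FPKM (−4.91 ± 0.04).

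Of 21 heat shock and chaperone genes, 15 rose and 6 fell, with a median of 1.77 (adjusted p = 2.29e-04; adjusted p = 0.489 with an estimated correlation). The members that fell included HSP12, a small heat shock protein, at 4417 ± 141 FPKM in control and 27.6 ± 3.87 under Amb (−7.28 ± 0.13). A second identifier carried the same values as HSP12 in every library, so the reads may be shared between them. Among 10 copper and zinc genes 7 rose and 3 fell, with a median of 1.05 (adjusted p = 0.0126; adjusted p = 0.261 with an estimated correlation). PRA1, a secreted zinc-binding protein, rose by 4.09 ± 0.14, and the zinc transporter gene ZRT1 by 3.29 ± 0.13. Phosphate uptake genes rose in 8 of 13 cases and fell in 2, with a median of 1.14 (adjusted p = 0.00929; adjusted p = 0.365 with an estimated correlation), including PHO89 (2.17 ± 0.27) and GIT2 (2.51 ± 0.08). Of 19 sulfur assimilation and methionine genes 15 fell and 2 rose, with a median of −2.53 (adjusted p = 0.0431; adjusted p = 0.513 with an estimated correlation). MET6, the methionine synthase gene, changed by −4.01 ± 0.07 and the methionine permease gene MUP1 by −3.95 ± 0.07. The sulfur call ended with a pseudocount of 5 (adjusted p = 0.0525), with a mean of at least 5 FPKM (adjusted p = 0.0565), with only the groups compared in the fit (adjusted p = 0.0608), without genes under 300 nt (adjusted p = 0.0503) and without genes with any 0 (adjusted p = 0.0547).

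Ergosterol genes did not move together under Amb. Of 25 members 9 rose and 12 fell, with a median of −0.48 (adjusted p = 0.613), and after median-of-ratios scaling 11 rose and 9 fell with a median of 0.19. ERG11, the lanosterol demethylase that azoles inhibit, rose from 51.5 ± 3.14 to 123 ± 5.86 FPKM (1.24 ± 0.08, adjusted p = 7.02e-07). ERG3, a sterol desaturase gene, rose from 12.8 ± 1.98 to 34.6 ± 4.73 FPKM (1.37 ± 0.15) and ERG6, a sterol methyltransferase gene, from 9.41 ± 0.788 to 49.7 ± 5.08 FPKM (2.28 ± 0.10). Among the members that fell, ERG1, for squalene epoxidase, fell from 52.4 ± 2.63 to 6.94 ± 1.64 FPKM (−2.77 ± 0.15), and ERG20, for farnesyl pyrophosphate synthase, changed by −3.76 ± 0.26. In the efflux list 12 of 19 genes fell and 4 rose (adjusted p = 0.613), a split that became 9 and 8 after scaling with the median moving from −0.79 to −0.05. MDR1, a major facilitator pump gene, changed by −4.34 ± 0.08. Of 39 antioxidant genes 23 fell and 11 rose (adjusted p = 0.831), a split that became 18 and 18 after scaling. CAT1, for catalase, fell from 822 ± 16.5 to 90.2 ± 5.12 FPKM (−3.17 ± 0.11). SOD5, for a cell-surface superoxide dismutase, rose from 14.4 ± 2.65 to 61.9 ± 3.35 FPKM (2.05 ± 0.15). SOD1, the copper and zinc superoxide dismutase gene, went from 209 ± 12.9 to 246 ± 17.3 FPKM (0.24 ± 0.08, adjusted p = 0.0184), a call that ended without control library 1 (adjusted p = 0.0654) or Amb library 2 (adjusted p = 0.0661), or with a length trend removed (adjusted p = 0.261), while after median-of-ratios scaling it stood at 1.02 (adjusted p = 9.11e-07). The iron permease gene FTR1 went from 20.02 ± 3.12 to 27.4 ± 3.76 FPKM (0.43 ± 0.15, adjusted p = 0.0231), with overlapping groups and no call when control library 2 (adjusted p = 0.0686) or 3 (0.0845), or Amb library 2 (0.0606) or 3 (0.0811), was left out or a length trend was removed (0.126), while after median-of-ratios scaling it stood at 1.18 (adjusted p = 5.76e-05). ECE1, which encodes the precursor of the toxin candidalysin, changed by −1.18 ± 0.10, and by −0.41 after median-of-ratios scaling (adjusted p = 0.0137).

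The 8 largest increases under Amb among genes with a symbol included those of AGA1, from 0.440 ± 0.442 to 355 ± 55.4 FPKM (7.98 ± 0.23), INN1 (7.17 ± 0.07), PGA37 (6.72 ± 0.12), IPK2 (6.40 ± 0.10), MRV4 (6.19 ± 0.17) and HPD1 (6.14 ± 0.10). NRG2 was listed at 0 in all 3 control libraries and at 160.5 ± 47.0 FPKM under Amb. GDH3, the glutamate dehydrogenase gene, rose from 17.2 ± 1.97 to 1935 ± 5.55 FPKM (6.74 ± 0.07), and PUT1, for proline oxidase, rose by 6.08 ± 0.06. Besides HSP12 and RPL9B, the largest decreases among genes with a symbol and no value of 0 in either group were those of ASR2, from 4614 ± 190.1 to 26.8 ± 3.21 FPKM (−7.38 ± 0.09), CSP37 (−7.20 ± 0.08) and the glycine decarboxylase gene GCV2 (−6.94 ± 0.13). Of the genes that passed the test 68.0% fell, and 50.9% fell after median-of-ratios scaling, under which 2299 rose and 2384 fell. With 3 libraries against 3, an exact test of a single gene cannot give a p below 0.1.

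The comparison of the combination with control asked what both compounds did together. The fall of ribosomal and fermentation genes was seen here too. CDR1, CDR2, SNQ2 and TAC1 of the efflux list stood above control. ALK8, TES1 and TES15 were among the 8 largest increases of genes with a symbol. CDR1 rose from 2585 ± 39.4 to 5021 ± 139.7 FPKM (0.96 ± 0.06, adjusted p = 2.64e-07). ALK8, a cytochrome P450 gene of the alkane-inducible family, rose from 3.56 ± 0.728 to 639 ± 18.9 FPKM (7.14 ± 0.11, adjusted p = 6.94e-11). Of 5962 genes, 1527 rose and 3647 fell, and 788 did not pass the test.

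Of 19 genes of efflux and lipid translocation, 13 rose and 5 fell with the combination, with a median of 0.96 (adjusted p = 4.03e-04; adjusted p = 0.312 with an estimated correlation). TAC1, the activator of CDR1 and CDR2, rose from 51.9 ± 1.88 to 378 ± 5.07 FPKM (2.84 ± 0.06). TPO3, a transporter gene of the polyamine family, fell from 11886 ± 283 to 1084 ± 84.9 FPKM (−3.46 ± 0.06), and MDR1 changed by −2.86 ± 0.08. The ergosterol list again went both ways, with 9 of 25 genes higher and 14 lower (adjusted p = 0.295) and a median of −0.59, and after scaling 14 rose and 8 fell with a median of 0.44. ERG11 reached 245 ± 21.1 FPKM (2.23 ± 0.08), ERG3 55.7 ± 7.33 FPKM (2.04 ± 0.15) and ERG6 166 ± 5.35 FPKM (adjusted p = 7.59e-10), while ERG1 stood at 12.5 ± 0.692 FPKM (−1.99 ± 0.15, and −0.94 after scaling). IDI1, for the isomerase that supplies isoprenoid units, fell from 208 ± 4.54 to 2.71 ± 1.36 FPKM (−5.89 ± 0.25) and ERG20 changed by −5.73 ± 0.26.

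All 73 cytosolic ribosomal protein genes fell with the combination, with a median of −7.59 (adjusted p = 3.08e-10; adjusted p = 0.258 with an estimated correlation). RPL40B fell from 8735 ± 1494 to 8.19 ± 3.67 FPKM (−9.95 ± 0.80), RPL15A changed by −9.58 ± 0.44 and RPL43A by −9.19 ± 0.35. RPL29 was listed at 0 in all 3 combination libraries and at 7967 ± 645 FPKM in control. At coding lengths of 159 and 192 nt, RPL40B and RPL29 belong to the length class most often listed at 0 with the combination. The size of their changes may depend on length. Ribosome biogenesis genes fell in 58 of 63 cases and rose in 4, with a median of −3.27 (adjusted p = 1.76e-04; adjusted p = 0.364 with an estimated correlation), and NOP15 and UTP8 changed by −5.73 and −5.24. Of 27 proteasome genes 26 fell and none rose, with a median of −1.82 (adjusted p = 0.00606; adjusted p = 0.258 with an estimated correlation), a call that ended after median-of-ratios scaling (adjusted p = 0.0964), under which 17 fell and 7 rose. PRE10 and PRE2 changed by −4.00 ± 0.20 and −3.85 ± 0.16.

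Glycolysis and fermentation genes fell in 17 of 18 cases, with a median of −3.81 (adjusted p = 2.21e-04; adjusted p = 0.263 with an estimated correlation). PDC11 reached 26.0 ± 1.14 FPKM (−7.35 ± 0.09) and TDH3, for glyceraldehyde phosphate dehydrogenase, fell from 10478 ± 305 to 173 ± 13.8 FPKM (−5.91 ± 0.06). The member that rose was ADH2, an alcohol dehydrogenase gene, at 278 ± 16.1 FPKM in control and 633 ± 4.44 with the combination (1.19 ± 0.08). Respiratory chain and ATP synthase genes fell in 31 of 35 cases and rose in 4, with a median of −3.13 (adjusted p = 0.00252; adjusted p = 0.364 with an estimated correlation), and COX9 and QCR9 were listed at 0 in all 3 combination libraries. Trehalose, glycogen and glycerol genes fell in 13 of 16 cases and rose in 1, with a median of −2.09 (adjusted p = 0.0328; adjusted p = 0.364 with an estimated correlation), and after median-of-ratios scaling the call ended (adjusted p = 0.0964), with 10 lower and 4 higher. TPS1, the trehalose phosphate synthase gene, changed by −5.15 ± 0.23. Glyoxylate cycle, fatty acid oxidation and gluconeogenesis genes rose in 21 of 29 cases and fell in 5, with a median of 1.23 (adjusted p = 1.23e-06; adjusted p = 0.364 with an estimated correlation), among them POX1 (3.86 ± 0.07), the carnitine acetyltransferase gene CAT2 (2.49 ± 0.08) and the peroxisomal import receptor gene PEX5 (2.23 ± 0.07).

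Heat shock and chaperone genes rose in 15 of 21 cases and fell in 6, with a median of 2.21 (adjusted p = 9.37e-05; adjusted p = 0.364 with an estimated correlation). HSP104 reached 9667 ± 592 FPKM, whereas SSB1, a ribosome-associated chaperone gene, fell from 1014 ± 53.8 to 21.5 ± 0.609 FPKM (−5.50 ± 0.08). Copper and zinc genes rose in 7 of 10 cases and fell in 3, with a median of 0.87 (adjusted p = 0.0114; adjusted p = 0.263 with an estimated correlation), and ZRT1 and ZRT2, both zinc transporter genes, moved apart (2.84 ± 0.13 and −3.66 ± 0.15). Iron uptake genes rose in 11 of 23 cases and fell in 7, with a median of 0.57 (adjusted p = 0.0266; adjusted p = 0.375 with an estimated correlation), including the reductase gene FRE9 (3.59 ± 0.13) and the multicopper oxidase gene FET34 (−3.51 ± 0.08). Phosphate uptake genes rose in 7 of 13 cases and fell in 5, with a median of 0.81 (adjusted p = 0.0408; adjusted p = 0.364 with an estimated correlation), and PHO87 and PHO114 changed by −3.19 ± 0.15 and 2.75 ± 0.12. Opaque-cell markers rose in 6 of 12 cases and fell in 4, with a median of 0.40 (adjusted p = 0.0491; adjusted p = 0.364 with an estimated correlation). WOR2, a regulator of the switch between white and opaque cells, rose from 29.3 ± 1.32 to 294 ± 7.09 FPKM (3.28 ± 0.08). The phosphate call ended after median-of-ratios scaling (adjusted p = 0.0847), after rescaling to a common sum (adjusted p = 0.0578), with a mean of at least 5 FPKM (adjusted p = 0.122), without genes with any 0 (adjusted p = 0.0501) and with a length trend removed (adjusted p = 0.0509). The iron call ended with a mean of at least 5 FPKM (adjusted p = 0.0972) and without genes with any 0 (adjusted p = 0.0501). After median-of-ratios scaling 16 iron uptake genes rose and 4 fell, with a median of 1.03. The opaque-cell call ended after median-of-ratios scaling (adjusted p = 0.0847), with quantile normalization (adjusted p = 0.0583), with a pseudocount of 0.1 (adjusted p = 0.0573), with a mean of at least 5 FPKM (adjusted p = 0.0636), without genes with any 0 (adjusted p = 0.0584), with a length trend removed (adjusted p = 0.0946) and without control library 1 (adjusted p = 0.0537) or combination library 3 (adjusted p = 0.0609).

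Besides ALK8, the largest increases among genes with a symbol were those of ADH3, an alcohol dehydrogenase gene, from 3.73 ± 0.761 to 559.6 ± 15.3 FPKM (6.90 ± 0.12), the acyl-CoA thioesterase genes TES1 (6.56 ± 0.15) and TES15 (6.38 ± 0.12), PRC2 (6.43 ± 0.13), INN1 (6.97 ± 0.07) and GDH3 (7.58 ± 0.07). INO1, the inositol phosphate synthase gene, rose from 6.12 ± 1.26 to 569 ± 16.8 FPKM (6.34 ± 0.13). CAT1 fell to 24.0 ± 4.17 FPKM (−5.05 ± 0.11), SOD1 rose to 372 ± 24.1 FPKM (0.83 ± 0.08) and ECE1 changed by −1.39 ± 0.10. After median-of-ratios scaling SOD1 stood at 1.92 and ECE1 at −0.31 (adjusted p = 0.0400). SOD5 (0.00 ± 0.15, adjusted p = 0.999) and FTR1 (−0.24 ± 0.15, adjusted p = 0.161) did not pass the test, while after median-of-ratios scaling SOD5 stood at 1.01 (adjusted p = 7.83e-05) and FTR1 at 0.79 (adjusted p = 7.42e-04), and with a length trend removed FTR1 passed as lower (−0.41, adjusted p = 0.0282). Of the genes that passed the test 70.5% fell, and 52.0% after scaling, under which 2333 rose and 2524 fell.

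**Figure D2:**
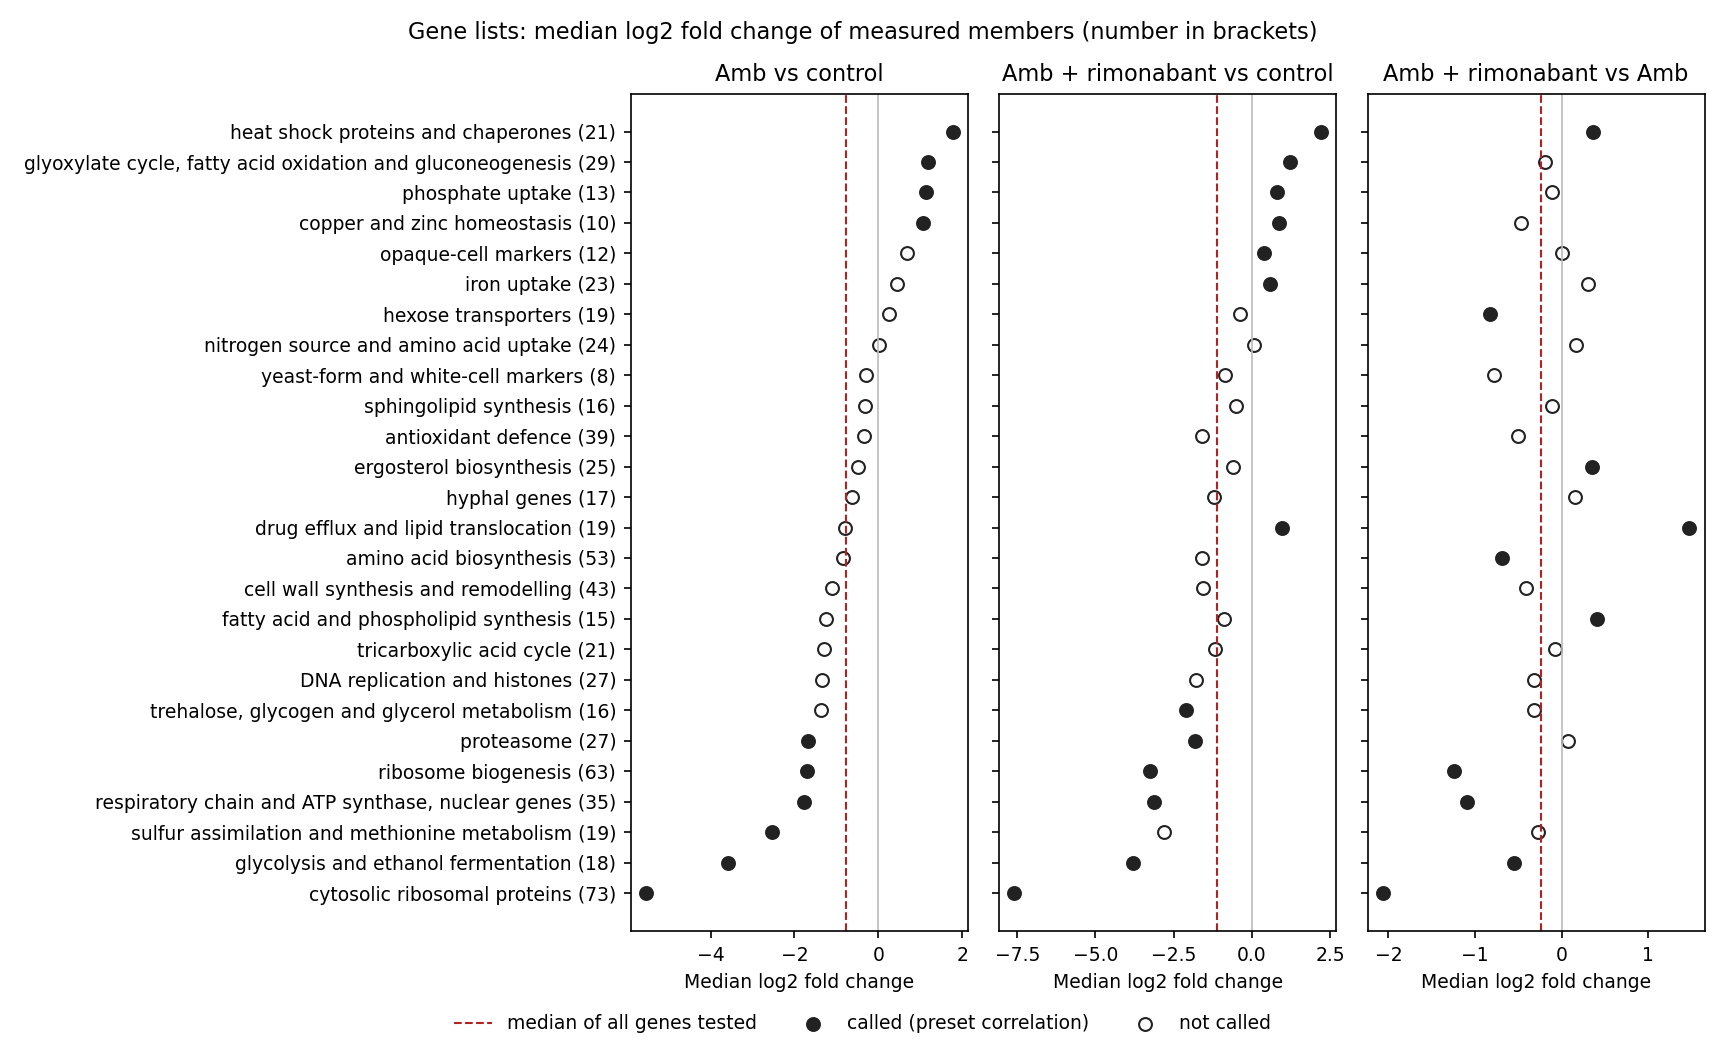
Each circle is the median log2 fold change (x axis) of the measured members of 1 of 26 gene lists (y axis, number of members in brackets) in 1 of the 3 comparisons (panels), filled where the list test passed with the preset correlation, and the dashed line is the median of all genes tested. Cytosolic ribosomal proteins lie lowest in each panel (−5.54, −7.59 and −2.06), and none of the filled circles kept its call with an estimated correlation.

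The comparison of the combination with Amb asked what rimonabant added. CDR2, CDR1 and SNQ2 of the efflux list, in which 13 of 19 genes rose and 5 fell, were among the 8 largest increases of genes with a symbol. CDR2 (CAALFM_C304890WA), an ABC transporter gene of azole efflux, stood at 20.7 ± 0.233 FPKM under Amb and 682 ± 41.3 with the combination, a change of 4.98 ± 0.06 (adjusted p = 1.94e-10). CDR1 went from 269 ± 19.7 to 5021 ± 139.7 FPKM (4.22 ± 0.06, adjusted p = 2.45e-10). The ribosomal protein list (64 of 73 lower and 1 higher) and the respiratory list (30 of 35 lower and 3 higher) passed the test as lower here too, with the preset correlation only. Of 5962 genes 1237 rose and 2270 fell, and 2455 did not pass the test.

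Of 19 genes of efflux and lipid translocation, 13 rose, 5 fell and 1 did not pass the test, with a median of 1.48 (adjusted p = 3.08e-06; adjusted p = 0.363 with an estimated correlation). SNQ2, another ABC transporter gene, rose from 112 ± 6.63 to 1404 ± 3.72 FPKM (3.64 ± 0.05, adjusted p = 5.04e-10). TAC1 rose from 45.1 ± 2.14 to 378 ± 5.07 FPKM (3.04 ± 0.06, adjusted p = 3.31e-09). Not every efflux gene followed: TPO3 fell from 3723 ± 115 to 1084 ± 84.9 FPKM (−1.78 ± 0.06), and MDR1 rose to 73.8 ± 3.39 FPKM (1.48 ± 0.08) but stayed below its control level of 541 ± 18.2 FPKM.

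The ergosterol list and the fatty acid and phospholipid list passed the test as higher, while the sphingolipid list did not pass (6 of 16 higher and 7 lower, adjusted p = 0.573, and 7 and 4 after median-of-ratios scaling). Of 25 ergosterol genes 12 rose and 5 fell, with a median of 0.35 (adjusted p = 0.0124; adjusted p = 0.455 with an estimated correlation). ERG6 rose by 1.72 ± 0.10, ERG11 by 0.99 ± 0.08 (adjusted p = 9.98e-06), ERG3 by 0.67 ± 0.15 and ERG1 by 0.78 ± 0.15. ERG24, for a sterol reductase, rose from 7.09 ± 0.439 to 31.5 ± 4.66 FPKM (2.00 ± 0.13). The members that fell included ERG28, for a scaffold protein of the pathway (−2.42 ± 0.21), and IDI1 (−2.32 ± 0.25). Fatty acid and phospholipid synthesis genes rose in 10 of 15 cases and fell in 3, with a median of 0.41 (adjusted p = 0.00636; adjusted p = 0.432 with an estimated correlation). FAS2, for the alpha subunit of fatty acid synthase, rose from 11.9 ± 0.478 to 42.5 ± 4.55 FPKM (1.75 ± 0.10), still below 230.4 ± 15.5 FPKM in control, and INO1 rose by 1.91 ± 0.13.

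**Figure D3:**
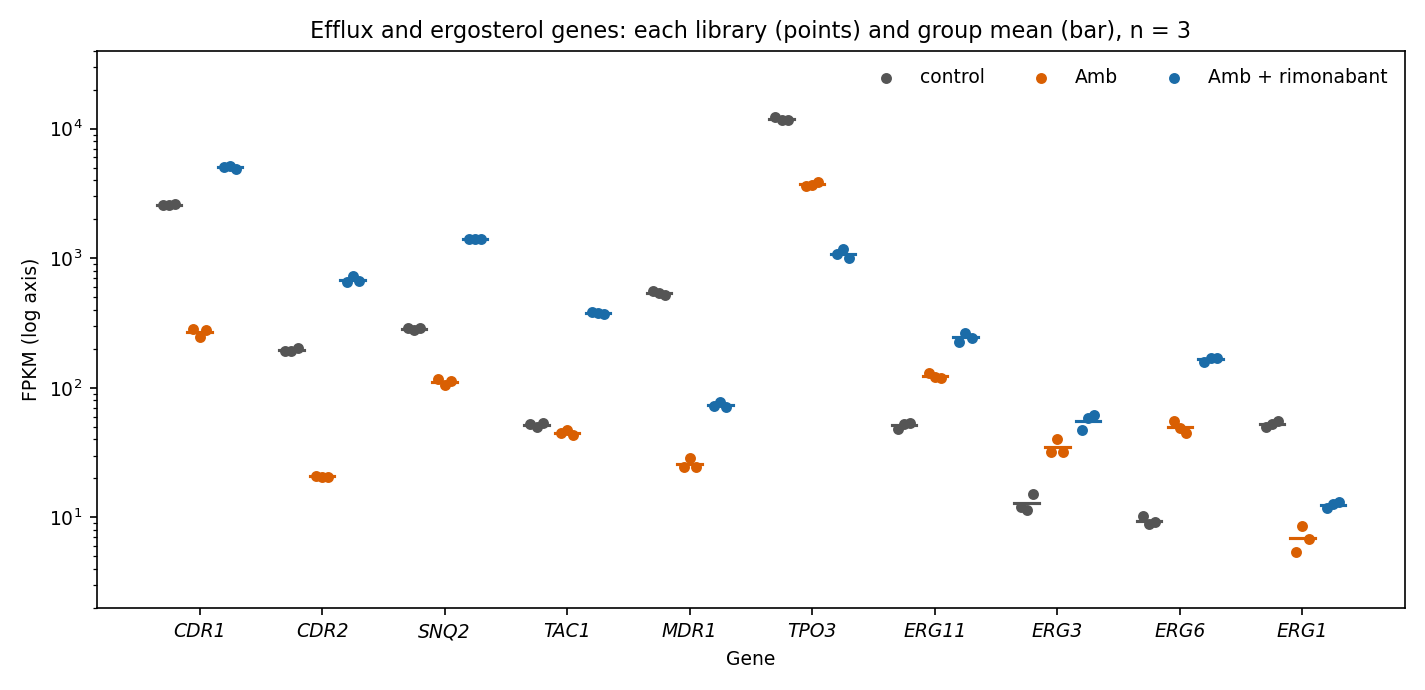
Points are the FPKM of 6 genes of the efflux list and 4 ergosterol genes (x axis) in each library (y axis, log scale) and bars are group means (n = 3), coloured by group. CDR1 stood at 2585 FPKM in control, 269 under Amb and 5021 with the combination, while ERG11 stood at 51.5, 123 and 245 FPKM.

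Cytosolic ribosomal protein genes fell in 64 of 73 cases and rose in 1, with a median of −2.06 (adjusted p = 1.50e-09; adjusted p = 0.363 with an estimated correlation). RPL39 fell from 487 ± 87.2 to 35.1 ± 14.1 FPKM (−3.81 ± 0.25), and RPL29, at 144 ± 56.7 FPKM under Amb, was listed at 0 in all 3 combination libraries. RPS30 was listed at 0 in 2 of the 3 combination libraries. Of 63 ribosome biogenesis genes 42 fell and 3 rose, with a median of −1.24 (adjusted p = 2.95e-04; adjusted p = 0.455 with an estimated correlation), among them GAR1 (−3.60 ± 0.24) and SSF1 (−3.29 ± 0.31). NOP10 of this list also passed the test, but its call ended with a robust variance model (adjusted p = 0.0590) or only the groups compared in the fit (0.0809). It also ended with a length trend removed (0.213), without Amb library 2 (0.110) or 3 (0.111), and without any 1 of the combination libraries (0.0725 to 0.0733). Respiratory chain and ATP synthase genes fell in 30 of 35 cases and rose in 3, with a median of −1.09 (adjusted p = 1.16e-04; adjusted p = 0.432 with an estimated correlation). COX9, a cytochrome oxidase subunit gene, was at 1158 ± 52.6 FPKM under Amb and listed at 0 in all 3 combination libraries, as were QCR9 (254 ± 116 FPKM under Amb) and COX17 (307 ± 122 FPKM under Amb), which encodes a copper chaperone of cytochrome oxidase. TOM7, for a subunit of the mitochondrial import channel, was listed at 0, 0 and 123 FPKM, and ATP18 at 0, 0 and 70.2 FPKM. Genes listed at 0 were mostly short. In longer genes, too, the change between the treated groups followed length, as given under other observations. Removing a length trend left 30 of the 33 list calls and 282 of 286 values for named genes the same. Among genes with a coding length up to 200 nt and at least 10 FPKM in another group, 75.8% were listed at 0 in all 3 combination libraries, against 6.25% in the Amb libraries and 3.23% in the control libraries. Among the 26 respiratory genes longer than 400 nt, 21 fell and 3 rose, with a median of −1.04 against −0.20 for all genes of that length (unadjusted p = 5.62e-04; p = 0.130 with an estimated correlation).

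**Figure D4:**
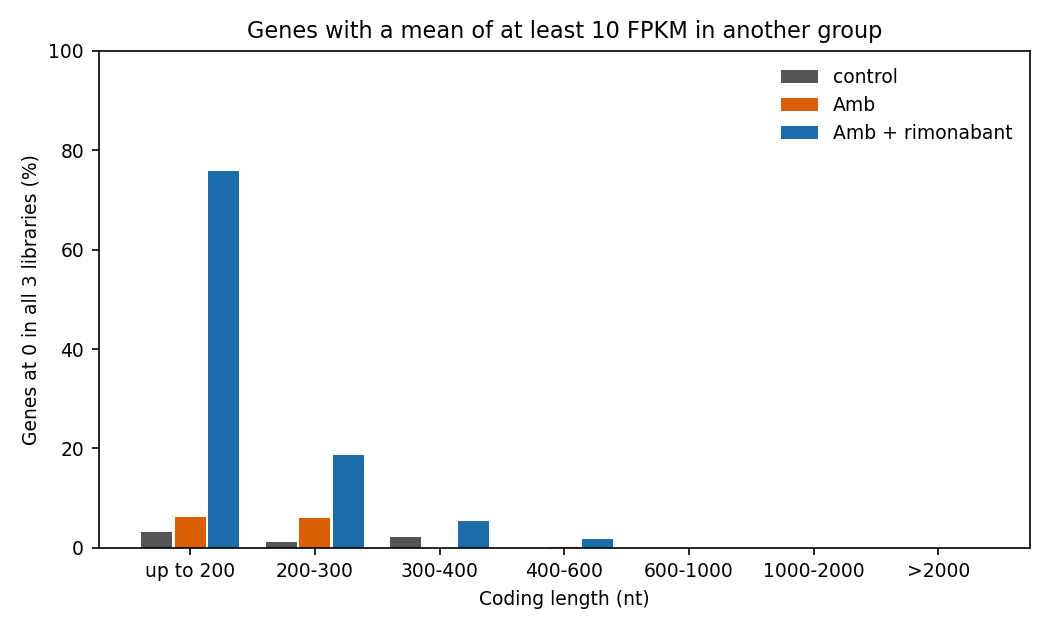
Bars show the percentage of genes listed at 0 in all 3 libraries of a group (y axis) by coding length class in nucleotides (x axis), for genes with a mean of at least 10 FPKM in another group. With the combination it was 75.8% up to 200 nt and 0% in each class above 600 nt.

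The lists of amino acid biosynthesis, hexose transporters and glycolysis passed the test as lower. Of 53 amino acid biosynthesis genes 32 fell and 4 rose, with a median of −0.69 (adjusted p = 0.0124; adjusted p = 0.455 with an estimated correlation). ARG3, for ornithine carbamoyltransferase, fell from 221 ± 24.5 to 19.7 ± 4.01 FPKM (−3.43 ± 0.15), LEU1, an enzyme gene of leucine synthesis, changed by −2.63 ± 0.08, and TRP5, for tryptophan synthase, by −2.32 ± 0.13. Hexose transporter genes fell in 13 of 19 cases and rose in 2, with a median of −0.82 (adjusted p = 0.0269; adjusted p = 0.432 with an estimated correlation). HGT17 fell from 2482 ± 166 to 493 ± 27.4 FPKM (−2.33 ± 0.08), and HXT5 and HGT12 changed by −1.95 and −1.94. Glycolysis and fermentation genes fell in 13 of 18 cases and rose in 2, with a median of −0.55 (adjusted p = 0.0269; adjusted p = 0.455 with an estimated correlation). TDH3 changed by −1.93 ± 0.06, while ADH2 rose from 119 ± 12.0 to 633 ± 4.44 FPKM (2.41 ± 0.08). After median-of-ratios scaling the hexose transporter call ended (adjusted p = 0.0576), as did that of glycolysis (adjusted p = 0.256), with 7 of 18 lower and 2 higher. The glycolysis call also ended after rescaling to a common sum (adjusted p = 0.208), with quantile normalization (adjusted p = 0.144), with a mean of at least 5 FPKM (adjusted p = 0.0584), without a mean-variance trend (adjusted p = 0.0501), with a length trend removed (adjusted p = 0.0555) and without combination library 2 (adjusted p = 0.0637).

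Heat shock and chaperone genes rose in 13 of 21 cases and fell in 5, with a median of 0.36 (adjusted p = 0.00636; adjusted p = 0.481 with an estimated correlation). HSP78, a mitochondrial disaggregase gene, rose from 1049 ± 40.5 to 2425 ± 115 FPKM (1.21 ± 0.06), while SSB1 (−1.33 ± 0.08) and HSP30 (−1.16 ± 0.16) fell. In the antioxidant list, 23 of 39 genes fell and 7 rose (adjusted p = 0.197). CAT1 changed by −1.88 ± 0.11, and SOD5 fell from 61.9 ± 3.35 to 14.3 ± 2.18 FPKM (−2.05 ± 0.15), while SOD1 rose by 0.59 ± 0.08. FTR1 changed by −0.67 ± 0.15, a call that ended with quantile normalization (−0.25, adjusted p = 0.166). ECE1 did not pass the test (−0.20 ± 0.10, adjusted p = 0.103), but did without combination library 3 (−0.28, adjusted p = 0.0473), and its value was 0.09 after median-of-ratios scaling (adjusted p = 0.553).

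Other large increases were those of DAL52, an allantoate permease family gene, from 4.73 ± 0.246 to 146 ± 13.7 FPKM (4.67 ± 0.14), SFH5, a phosphatidylinositol transfer protein gene (4.59 ± 0.21), ALK8 (4.33 ± 0.11), the secreted protease gene SAP3 (4.22 ± 0.14) and PRC2 (3.94 ± 0.13). SAP3 lies past the 3′ end of CDR1, so reads from CDR1 are not excluded there. Besides RPL39 and GAR1, the largest decreases among genes with a symbol and no value of 0 in either group, listed in place of the shortest genes after the values were seen, were those of RPB8, an RNA polymerase subunit gene (−4.47 ± 0.34), the mitochondrial ribosomal genes MRP17 (−4.23 ± 0.33) and MRPL3 (−3.74 ± 0.08), APA2 (−3.89 ± 0.18), AGA1 (−3.70 ± 0.23) and FGR17 (−3.55 ± 0.23). Of the genes that passed the test 64.7% fell, and 48.8% after median-of-ratios scaling, under which 1838 rose and 1753 fell.

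The changes against control under Amb and with the combination had much in common. In both comparisons 1226 genes rose and 3039 fell, where independent calls would give 402 and 2036. Among the shared increases were GDH3, INN1, HSP104 and POX1, and among the shared decreases PDC11, ENO1, CAT1 and IDI1. Another 157 genes rose under Amb and fell with the combination, and 100 did the opposite, CDR1 and CDR2 among them. After median-of-ratios scaling 42 of the 157 and 37 of the 100 still passed in both directions. Across genes, both sets of log2 fold changes correlated with r = 0.862, and their covariance was 4.26. Both comparisons used the same 3 control libraries, which alone gave a covariance of 0.0576, r = 0.503 and a mean of 0 genes shared as higher and 0.01 as lower over 100 draws of simulated unchanged groups. No gene was changed in those draws, so few could pass in either comparison. Their shared counts therefore do not show how the common controls affect the overlap of changed genes. The 3 controls are too few to be split, so part of the excess of shared genes may come from them. The covariance lay 4.21 above the simulated value.

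For the lists that did not pass the test under Amb against control, the members split as follows. Tricarboxylic acid cycle genes rose in 5 of 21 cases and fell in 15, cell wall genes rose in 11 of 43 and fell in 26, amino acid biosynthesis genes rose in 14 of 53 and fell in 32, and iron uptake genes rose in 13 of 23 and fell in 7. Sphingolipid genes rose in 4 of 16 cases and fell in 10, fatty acid and phospholipid genes rose in 4 of 15 and fell in 8, DNA replication and histone genes rose in 2 of 27 and fell in 22, and trehalose, glycogen and glycerol genes rose in 2 of 16 and fell in 12. Hyphal genes rose in 8 of 17 cases and fell in 9, yeast-form and white-cell markers rose in 2 of 8 and fell in 5, opaque-cell markers rose in 7 of 12 and fell in 5, and nitrogen source and amino acid uptake genes rose in 10 of 24 and fell in 11. Of these 12 lists, the median of the sphingolipid list (−0.31 to 0.47) and of the yeast-form and white-cell list (−0.29 to 0.50) changed sign after median-of-ratios scaling, and their splits became 10 higher and 4 lower, and 5 and 3. After scaling the split was 20 and 23 for amino acid biosynthesis, 17 and 21 for the cell wall, 8 and 8 for hyphal genes and 13 and 8 for nitrogen source and amino acid uptake. Adjusted over the list alone, the counts of members that rose and fell were unchanged for 23, 26 and 18 of the 26 lists in the 3 comparisons. The exceptions under Amb against control were efflux (5 higher and 12 lower), fatty acid and phospholipid synthesis (4 and 9) and nitrogen source and amino acid uptake (11 and 11). For the combination against Amb, adjusted over the list alone, the counts became 1 higher and 66 lower for ribosomal proteins, 2 and 14 for glycolysis, 2 and 14 for hexose transporters, 8 and 24 for antioxidant genes, 10 and 5 for iron uptake, 9 and 10 for the tricarboxylic acid cycle, 1 and 7 for DNA replication and histones, and 4 and 5 for phosphate uptake. The signs of the median, the mean and the test differed in 4, 6 and 7 lists in the 3 comparisons, none of which passed the test.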

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

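The tests of FPKM ratios for neighbours past the 3′ end of a gene and the count of opposite changes after scaling were chosen only after the result was seen. Each result here was picked out because the effects of Amb alone and of the combination, both against control, had opposite signs and the direct comparison of the treated groups also passed the test. This held for 157 genes higher under Amb and lower with the combination, and for 100 genes lower under Amb and higher with the combination. Of these, 71 and 53 had a symbol, and 7 and 0 had a value of 0 in any library. Their median coding lengths were 954 and 1530 nt, against 1248 nt for all genes tested.

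Of the named genes in these sets, 6 kept opposite and significant signs after median-of-ratios scaling. CDR2 changed by −3.18 under Amb and 1.79 with the combination, a difference of 4.98. For CDR1 the values were −3.26 and 0.96, a difference of 4.22. The values of SNQ2 were −1.35 and 2.30, a difference of 3.64. SFH5 differed by 4.59 between −1.84 and 2.76. ADH2 differed by 2.41 between −1.22 and 1.19. PHO84, a phosphate transporter gene, went the other way, from 0.77 to −1.93, a difference of −2.69.

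For 5 further genes the opposite signs depended on the scaling, while the difference between the treated groups passed the test. DAL52 changed by −0.34 and 4.33, a difference of 4.67, and its value under Amb became 0.31 after scaling. TAC1 changed by −0.20 and 2.84, a difference of 3.04, with 0.57 under Amb after scaling. TEC1, a regulator of hyphal growth, changed by 0.41 and −0.43, a difference of −0.84, with 0.66 for the combination after scaling. FOX3, a thiolase gene, changed by 0.99 and −0.52, a difference of −1.51, with 0.52 for the combination after scaling. FGR17 changed by 2.91 and −0.65, a difference of −3.55, with 0.04 for the combination after scaling.

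CDR1 is also in 1 of 10 pairs of adjacent genes, formed by 16 of the 32 genes with a change of at least 3 for the combination against Amb. A shuffled gene order gave a mean of 0.170 pairs and at most 4 (permutation p = 1e-05, the smallest that the shuffles can give), which argues against adjacency by chance. Reads running past the end of a strongly raised gene would place the weaker gene past the 3′ end of the stronger, and this held for a share of 0.4 of the pairs (4 of 10, exact 95% interval 0.122 to 0.738), with 4 divergent pairs, in which such reads cannot reach the neighbour. In the 4 pairs with the weaker gene past the 3′ end, the FPKM ratio of the weaker to the stronger gene stayed within 2-fold over the 3 groups in 0. It varied 2.07-fold for SAP3 and CDR1 (1.91-fold between the nearest libraries), 2.31-fold for RAD57, 13.3-fold for YBL053 and 5.70-fold for CAALFM_CR09090CA. This does not exclude such reads, since transcripts of the weaker gene itself raise the ratio where the stronger gene is low. Reads past the end at a constant share cannot raise the ratio from Amb to the combination. For CAALFM_CR09090CA and CAALFM_CR09100CA it rose from 10.9% to 26.7%, and the lowest combination library lay 2.03-fold above the highest Amb library, which argues against such reads as the whole cause in that pair. For the other 3 pairs they stay open: the ratio went from 11.2% to 5.24% for RAD57 and from 6.54% to 6.21% for YBL053, and for SAP3 from 1.17% to 1.53% with overlapping libraries. Pairs in a run of genes are not independent, strandedness is unknown, and shared regulation by rimonabant remains an untested alternative.

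The counts of genes that passed the test were set against other splits of the same 6 libraries, with each comparison fitted to its own 6 libraries and not to all 9, so the counts differ from those given above. For Amb against control the real split gave 4981 genes and the highest of the other splits 2, for the combination against control 5178 and 0, and for the combination against Amb 3154 and 2. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.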

How the results depend on the processing

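The alternatives that left out genes under 300 nt, left out genes with any 0 or removed a length trend were chosen after seeing the data. Of 198 values for the 10 counts 186 stayed within 1.5 times the reported count, including all under the pseudocounts, filters, variance models and libraries left out. The other 12 came from scaling or from a minimum change, the latter by construction. Median-of-ratios scaling and quantile normalization bring the libraries to a common level, so their more even splits are also largely built in. Median-of-ratios scaling gave 2333 genes higher for the combination against control, 1911 higher in both comparisons with control and 1970 lower in both. Quantile normalization gave 2434 higher and 2403 lower for the combination against control, 2018 higher for the combination against Amb, 1972 higher in both and 1951 lower in both, and the cause was not tested beyond the shift of the median. A change of at least 1 left 444 higher and 1236 lower for the combination against Amb, and 23 and 13 genes of opposite direction. Of 693 values for the 33 list calls 69 lost the call, 33 of them with an estimated correlation, and 0 reversed. The other losses were for respiratory and sulfur genes under Amb, for iron, opaque-cell, phosphate, trehalose and proteasome genes with the combination against control, and for glycolysis and hexose transporters with the combination against Amb. Over all genes tested, 138, 281 and 0 passed in opposite directions as deposited and after median-of-ratios scaling in the 3 comparisons. TAC1 under Amb, and TEC1 and FOX3 with the combination against control, were among them. Named genes were followed only in the comparisons where the rule named them. Of 5676 such values 5645 were the same, 17 lost a call, 5 gained one and 9 reversed, all 9 for genes that had not passed the test in that comparison. The lost calls were those of SOD1 and FTR1 under Amb, and of NOP10 and FTR1 with the combination against Amb. SOD5 for the combination against control went from 0.00 to −7e-04 with a pseudocount of 5 and ranged from −0.14 to 0.11 with 1 library left out (−0.14 without control library 1 and −0.11 without combination library 2). FTR1 for the combination against control became 0.17 when rescaled to a common sum, 0.79 with median of ratios and 0.92 with quantile normalization. ECE1 for the combination against Amb became 0.088, 0.091 and 0.17 under the same 3. The cause was not tested. Depth is unknown and limits low values most.

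With the replicate block, the counts were 1553 higher and 3282 lower, 1510 and 3640, and 1177 and 2182 in the 3 comparisons, and 1217, 3010, 150 and 81 genes were shared as higher, lower, higher then lower and lower then higher. Deviations of libraries with the same number correlated at −0.0859 to 0.0718 over 9 pairs, and 4 of 9 libraries fitted best with their own number, so the numbers were not taken as pairs.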

Other observations

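The test of coding length among genes listed at 0, and that of a loss regardless of length, were chosen only after the result was seen. The cell wall list did not pass the test in any of the 3 comparisons, and single members changed. CHS3, for a chitin synthase, fell from 324 ± 21.2 FPKM in control to 18.5 ± 1.32 under Amb and 13.7 ± 1.26 with the combination (mean ± SD, n = 3), and GSC1, for the glucan synthase, changed by −3.94 ± 0.09 and −4.12 ± 0.09. KRE1, a gene of cell wall glucan assembly, fell from 288 ± 10.6 to 47.6 ± 12.5 FPKM between Amb and the combination (−2.60 ± 0.15). Of 43 cell wall genes 5 rose and 23 fell between those groups (adjusted p = 0.104), and 8 and 13 after median-of-ratios scaling. For the combination against control 11 rose and 30 fell (adjusted p = 0.499), and 15 and 23 after scaling. HWP1, a hyphal wall protein gene, fell from 564 ± 55.6 FPKM to 34.1 ± 3.29 and 31.9 ± 2.49, while SAP6, a secreted protease gene, rose from 27.6 ± 3.72 to 102 ± 9.03 FPKM between the treated groups (1.85 ± 0.14). WH11, a marker of white cells, stood at 89804 ± 7088 FPKM in control, 4169.7 ± 508 under Amb and 5656 ± 703 with the combination.

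In the tricarboxylic acid cycle list, LPD1, for the dihydrolipoamide dehydrogenase, rose from 941 ± 27.6 FPKM in control to 3286 ± 289 under Amb and 9999 ± 545 with the combination, whereas IDH1, an isocitrate dehydrogenase gene, changed by −2.97 ± 0.07 and −4.00 ± 0.07. Among sphingolipid genes, SCS7, for a ceramide hydroxylase, fell under Amb (−2.89 ± 0.06) and rose from 153 ± 9.05 to 828 ± 16.5 FPKM between the treated groups (2.43 ± 0.06). ARG1 and ARG4, the last steps of arginine synthesis, rose under Amb by 4.79 ± 0.07 and 4.84 ± 0.08. Among permease genes for amino acids, GAP4, GAP5 and GAP6 changed by −2.77 ± 0.06, −4.65 ± 0.09 and −2.02 ± 0.04 under Amb, and GAP6 fell from 1581 ± 46.7 to 489 ± 14.0 FPKM between the treated groups. RNR22, for a ribonucleotide reductase subunit, changed by −3.98 ± 0.16 under Amb. Of the 60 unmatched identifiers 38 were higher and 13 lower under Amb, 39 and 10 with the combination against control, and 18 and 24 between the treated groups.

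Short genes were listed at 0 with the combination far more often than long ones. Changes followed length beyond these values of 0. The median log2 fold change for the combination against Amb was −5.53 up to 200 nt, −1.22 from 200 to 300 nt and −0.69 from 300 to 400 nt. It was −0.56 from 400 to 600 nt, −0.44 from 600 to 1000 nt, −0.18 from 1000 to 2000 nt and 0.04 beyond. For Amb against control it was lowest in the longest genes, at −1.26 over 2000 nt. Of 3506 genes with at least 10 FPKM under Amb, 39 were at 0 in all 3 combination libraries. Their median coding length was 189 nt (bootstrap interval 186 to 219) against a lower quartile of 697.5 nt for all. An effect of length in the FPKM estimate would give such a value. The value restates the pattern that prompted the test, so it adds no separate support for that effect. The share at 0 over 1000 nt divided by that up to 200 nt was 0 (0 of 1997 genes against 23 of 31). This cannot decide about a loss of transcripts regardless of length. At equal FPKM a longer gene holds more fragments and reaches 0 less readily. The 26 respiratory members over 400 nt had a median of −1.04 against −0.20 for all genes of that length. With an estimated correlation the p of this list test was 0.130. Genes up to 400 nt alone thus do not account for the respiratory list. The call of the whole respiratory list for the combination against Amb also held with a length trend removed, with the preset correlation. Length is not fully excluded there, because the members were not matched by length and changes still followed length above 400 nt. A lower number of short transcripts in the cells stays open, and the values of 0 may not mean that a gene was silent.

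The lower median in both treated groups was weighed against composition. Rescaling on the genes outside the 100 with the largest share moved the median for Amb against control from −0.77 to −0.18 (−0.227 to −0.140 over pairs of libraries). The 100 genes held 35.1% to 35.4% of summed FPKM times coding length in control, 46.4% to 47.4% under Amb and 49.5% to 51.1% with the combination. The 60 unmatched identifiers had no coding length, so they entered neither the 100 genes nor the sum. The most abundant of them under Amb averaged 3536 FPKM in control, 87676 under Amb and 47596 with the combination. These shares therefore leave out a large change in composition, whose part in the median shift was not tested. The rescaling does not isolate this share, because the sum over the other genes also carries the library total. Dividing by that total alone moved the median to −0.43. Scaling on the bulk of the genes also tends to shrink their median shift by construction. The remainder was below −0.1, and how much the share accounts for stays open. Fragments outside annotated genes could not be judged: the corrected median was −0.43, but FPKM times coding length summed to 113% to 149% of the expected total, so it is not a share and the test is void. A true fall of most transcripts per cell under Amb was not tested, since no spike-in was described.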
